A study of Homo sapiens with 13 samples.

How the data were processed

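Gene expression was measured by RNA sequencing in 13 samples of 4 groups: CD3 T cells (3 libraries), CD4 T cells (2 libraries), T cell acute lymphoblastic leukaemia (T-ALL; 5 libraries of 3 patients) and thymus (3 libraries). Per the labels' protocols, polyadenylated RNA was made into strand-marking libraries with the dUTP method and read on a NextSeq instrument, as single reads of 50 bp or, for thymus, as pairs of 150 bp. The series' design text describes instead an unstranded kit, paired reads and a choice of polyadenylated or ribosome-depleted RNA, so strand use and read format are open. Per the submitters' processing notes, bcl2fastq, TopHat, HTSeq and edgeR were used with build hg19, without versions or settings.

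The authors deposited 3 tables, each setting T-ALL beside 1 normal group. The library columns hold CPM, reads per gene scaled to the library's total, that the authors computed from whole reads per gene. Dividing each deposited column by the value of 1 read gave whole numbers, within a tolerance of 0.01, for 100% of values. Any factor per library would pass that check. Columns of the CD3 and CD4 tables summed to 996457 to 998689 CPM, which leaves little room for further scaling. Library columns of the thymus table, which holds only part of the genes, summed to 116122 to 156566 CPM. Further scaling could not be checked there. The fold changes the authors deposited are log2 values of T-ALL over the normal group from their edgeR fit, and their average log2 CPM comes from the same fit. The likelihood ratio scores, p-values and adjusted p-values that the authors deposited come from that fit as well, per the file headers and the processing notes. The CD3 table held 16007 genes and the CD4 table held 15690, of which 15986 and 15672 were analysed after XIST, TSIX and genes of the Y chromosome had been left out. T-ALL values were the same in both tables (largest difference 0 CPM over 15508 shared genes). The thymus table held only 1545 protein-coding genes, all with a deposited adjusted p of at most 0.00998 and a log2 fold change of at least 1.03 in size, and its smallest adjusted p-values correspond to 16609 tests. Another T-ALL column of that table equalled the mean of its other 3 to within 6.67e-07 CPM and was not used as a library. Those 3 columns did not hold the values of the same-numbered libraries of the CD3 table (0 of 3; at most 2.44% of values were alike), so they were tied to the T-ALL group only, and T-ALL levels of the thymus table were compared with thymus alone. In all, 21 library columns were used. Gene symbols that had turned into dates (20, 20 and 4 genes) were restored from the gene IDs, of which 96.6%, 96.8% and 98.2% were in the name table of the reference. Coordinates are those of the files (hg19).

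Reads assigned to genes came to 20615894 to 25768047 per CD3 library, 25624268 to 26488816 per CD4 library and 20957106 to 32200855 per T-ALL library. In the thymus table they came to 20104637 to 22390454 per thymus library and 27687306 to 54354504 per T-ALL column, as computed from the value of 1 read. Totals of the thymus table hold only if its columns had no further scaling. A gene at 0 reads in a library could still have stood at up to 0.149 CPM (3 reads), and a fold against a group at 0 reads was computed against 3 reads over that group's libraries and is given as a lower bound. Such limits cover counting error only.

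For CD3 and CD4 T cells, CPM were scaled with edgeR's TMM factors, the libraries of a patient were averaged so that n counts patients, and log2(CPM + 0.5) was tested with limma (moderated test with a mean-dependent prior). Genes needed at least 1 CPM in as many units as the smaller group holds. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are limma's. Levels are mean CPM with the SD over patients or normal libraries. edgeR's quasi-likelihood test on counts had been fixed as the test before the data were examined. It was replaced because the tables hold CPM, and it was run on the recovered reads as an alternative. For thymus, the call is the authors' own, and its log2 fold changes and adjusted p-values are theirs, named as such. Whether their fit counted the averaged T-ALL column as a library is not known. If it did, their p-values are too small. Refits of that table on the recovered reads counted the genes it lacks as tested and unchanged.

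Before the data were examined, 21 gene lists and 6 lists of cell type markers (482 genes) had been fixed: SR proteins, SR protein kinases, hnRNP proteins, spliceosome core, USP deubiquitinases, proteasome, NOTCH1 pathway, T-ALL transcription factor oncogenes, genes recurrently altered in T-ALL, immature thymocyte, mature T cell, T cell receptor, cell cycle, ribosome biogenesis, immediate early, heat shock, NF-kappaB, interferon, antigen presentation, histone and mitochondrially encoded genes, and markers of cytotoxic T and NK, B, myeloid, erythroid and platelet lineages and of thymic stroma. Lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry, adjusted over the 24 lists with at least 3 members tested. For thymus, members in the deposited table were counted, and where at least 5 were there (8 lists) their split into higher and lower was set against that of the table's other genes by Fisher's exact test (two-sided), adjusted over the 8 lists. Named genes followed a rule fixed at the same time: the 10 largest rises and falls among called genes with an average log2 CPM of at least 3 and no overlap between the groups' libraries, the 5 genes SRSF6, SF3B1, USP7, NOTCH1 and MYC whatever their values, and up to 4 called members per list with the largest change. Immunoglobulin and T cell receptor segments, genes that are commonly deleted and clone names were not named. Genes outside this rule are said to have been chosen after their values were seen.

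The test was tried on simulated counts drawn from these libraries' means and depths with a known set of changed genes. For CD3 T cells (14735 genes) it called 10% of genes changed 2-fold, 91.5% at 4-fold and 100% at 8-fold, and 4.64% of calls were false. For CD4 T cells (14718 genes) the shares were 10%, 79.2% and 100%, with 7.28% of calls false. The simulation gave all genes and both groups the same spread, and 193 and 195 of the tested genes were changed. In the data T-ALL patients varied more than normal libraries and far more genes were called. The shares therefore hold for the simulated setting only. Alternatives covered scaling, filter, pseudocount, test, unit of replication, threshold, set test and leaving out each library or patient. Comparisons with the study's cell lines and drugs were not analysed here, nor was exon usage, which gene totals do not hold. Some single genes are not reported here. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.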

Results

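Messenger RNA levels were measured by sequencing in leukaemic and normal T-lineage cells. The T-ALL group, an aggressive leukaemia of immature T cells, held 5 libraries of 3 patients. The normal groups were CD3 T cells (T cells of every kind, 3 libraries), CD4 T cells (the helper subset, 2 libraries) and thymus, the organ in which T cells mature (3 libraries). The series asks how the splicing machinery is regulated in this leukaemia, so its comparisons set T-ALL against each normal group. Between 20104637 and 32200855 reads per library were assigned to genes, and between 27687306 and 54354504 per T-ALL column of the thymus table. Those of the thymus table hold only if its columns were scaled to the library's total alone. Libraries of different T-ALL patients were less alike than those of any normal group: 21.3% to 40.1% of genes differed over 2-fold between patients, against 0.0399% to 10.6% between CD3 libraries and 0.182% between the pair of CD4 libraries. CD3 replicates 1 and 2 and the CD4 pair stood far closer to each other than other libraries did. It remains open whether their spread is technical and p-values against them too small.

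T-ALL cells differed from CD3 T cells in higher levels of cell division and immature thymocyte genes and lower levels of many genes of mature and cytotoxic T cells. TOP2A, the topoisomerase of DNA replication and mitosis, stood at 736 ± 190 CPM in T-ALL (SD, n = 3 patients) and 11.3 ± 6.83 CPM in CD3 T cells (SD, n = 3), 65.1 times higher. CCL5, a chemokine of effector T cells, stood at 0.476 ± 0.349 CPM in T-ALL and 746 ± 327 CPM in CD3 T cells, 1568 times lower in T-ALL. SRSF6, the splicing factor at the centre of the study's question, did not pass the test, at 345 ± 21.2 CPM in T-ALL and 361 ± 63.1 CPM in CD3 T cells. Of 14413 genes tested with limma, 5466 were called, 2666 higher and 2800 lower in T-ALL. Of 24 gene lists camera called 11, and 0 with an estimated correlation (2 at an unadjusted p under 0.05), where fry called 16.

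Among the largest rises stood thymocyte and cell division genes. CD1B, which presents lipid antigens and is made by cortical thymocytes, stood at 509 ± 359 CPM in T-ALL and 0.0291 CPM (2 reads) in CD3 T cells (limma, adjusted p = 4.27e-04). ARPP21 (355 ± 323 CPM against 0.0697 CPM; log2 fold change 8.94 ± 0.59, SE) and CD1E (8.81 ± 1.53) rose as well. FAT1, a cadherin (7.90 ± 0.88), MYO7B, a myosin (1337 ± 2156 CPM against 0.686 CPM), and DNTT, which adds bases at rearranging receptor genes (7.03 ± 1.86), followed. So did NOTCH3, at 499 ± 447 CPM against 0.0135 CPM (1 read), and the division genes TROAP (6.32 ± 0.39), UBE2C (6.31 ± 0.34) and GTSE1 (6.28 ± 0.41). The largest falls were led by effector and antigen presentation genes. Beside CCL5 these were CD74, the invariant chain of MHC class II (log2 fold change -8.40 ± 0.69), and GNLY, the pore-forming granulysin (-7.68 ± 0.39). The granzymes GZMH (-8.17 ± 0.77) and GZMK (-7.63) and the class II chain HLA-DPB1 (-7.58 ± 0.52) fell with them. NELL2, the cytokine receptor IL6R, SAMD3 and TRABD2A made up the rest, at log2 fold changes of -8.33, -7.74, -7.83 and -7.48. Adjusted p (limma) of these 20 genes lay between 1.42e-04 and 0.0271. Without any 1 CD3 library NOTCH3 (0.0578 to 0.0619) and DNTT (0.0822 to 0.0881) were not called. DNTT also lost its call without 1 or another of the patients (0.0740 and 0.0669).

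Most genes of the core splicing machinery rose. Of 28 genes of the spliceosome core (proteins of the U1, U2 and U5 particles), 22 rose and 1 fell, or 25 and 1 adjusted over the list alone. Together they had a median log2 fold change of 0.82 (camera adjusted p = 6.30e-08; adjusted p = 0.343 with an estimated correlation). SNRPD1, an Sm protein common to these particles, stood at 136 ± 19.9 CPM against 31.5 ± 5.69 CPM (log2 fold change 2.18 ± 0.19, adjusted p = 4.86e-04). SNRPC, SNRPF and SNRPD3 rose by log2 values of 1.91, 1.89 and 1.71. The member that fell was SF3B1, the U2 subunit that contacts the branch point: 539 ± 53.4 CPM against 1188 ± 345 CPM (log2 fold change -1.04 ± 0.26, adjusted p = 0.0217). Of 24 hnRNP genes, whose proteins bind pre-mRNA and often oppose exon inclusion, 20 rose and 0 fell, the same counts as adjusted over the list alone. The median log2 fold change was 0.98 (camera adjusted p = 1.89e-07; adjusted p = 0.410 with an estimated correlation). HNRNPAB (4.22 times higher) and HNRNPD (log2 fold change 1.64 ± 0.22) led among the abundant ones. SF3B1 lost its call without CD3 replicate 2 (adjusted p = 0.0551) and with CD3 replicates 1 and 2 averaged (0.0536), within a range of 9.01e-04 to 0.0551 over 22 settings.

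The SR proteins, which promote exon inclusion, moved both ways. Of 12 tested, SRSF1, SRSF2, SRSF3, SRSF4 and TRA2B rose and SRSF5 fell, or 6 up and 2 down adjusted over the list alone (camera adjusted p = 0.217). TRA2B rose from 224 ± 15.1 to 396 ± 78 CPM (log2 fold change 0.88 ± 0.19, adjusted p = 0.0134) and SRSF3 from 348 ± 26.2 to 569 ± 106 CPM. SRSF5 fell from 829 ± 96 to 453 ± 31.8 CPM (-0.80 ± 0.17, adjusted p = 0.0132). SRSF6 had a log2 fold change of 0.02 ± 0.18 (adjusted p = 0.950). Among 8 kinases of SR proteins, SRPK1 rose (0.94 ± 0.17) while CLK1 (-1.49 ± 0.27) and CLK4 (-1.45 ± 0.24) fell (the same counts adjusted over the list alone; camera adjusted p = 0.490). None of these 6 SR proteins was called in the authors' own fit (0 of 6; adjusted p 0.0554 for SRSF5 to 0.172 for SRSF2). TRA2B and SRSF5 lost their calls without CD3 replicate 1 (adjusted p = 0.0578 and 0.0552). SRSF3 and SRSF4 lost theirs without CD3 replicate 1 (0.0958 and 0.0985) or 2 (0.0870 and 0.0950) or 1 of the patients (0.0549 and 0.0640). In hg19 coordinates of the files, SRSF6 (ENSG00000124193) lies on chromosome 20 from 42086568 to 42092245, SF3B1 (ENSG00000115524) on chromosome 2 from 198254508 to 198299815 and USP7 (ENSG00000187555) on chromosome 16 from 8985951 to 9058371. NOTCH1 (ENSG00000148400) lies on chromosome 9 from 139388896 to 139440314 and MYC (ENSG00000136997) on chromosome 8 from 128747680 to 128753674. The plot of the 5 preselected genes shows SRSF6 in every group near the same level and SF3B1 lowest in T-ALL.

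**Figure D1:**
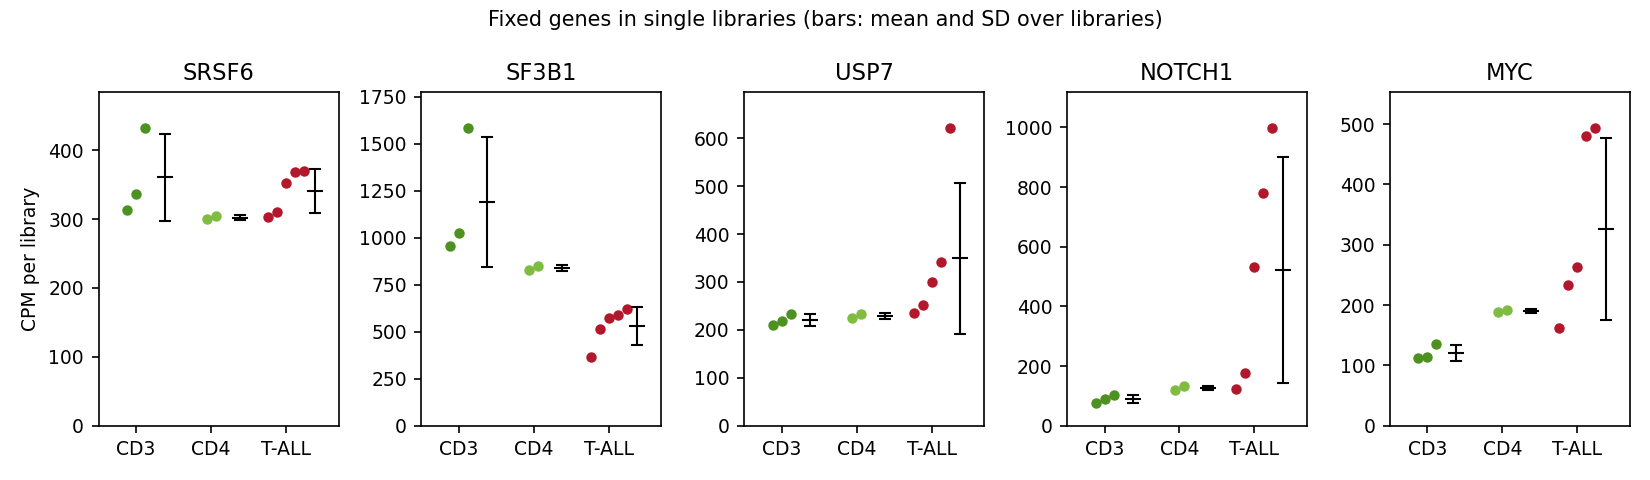
CPM of SRSF6, SF3B1, USP7, NOTCH1 and MYC in each CD3, CD4 and T-ALL library (points), with the mean and SD over libraries (bars; the 5 T-ALL libraries come from 3 patients, and the SDs in the text are over patients). SF3B1 means were 1188 CPM in CD3, 839 CPM in CD4 and, over patients, 539 CPM in T-ALL, and T-ALL libraries spread widely for NOTCH1 and MYC.

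Genes of protein turnover were tested as well, since the study asks about regulation after translation. Of 38 proteasome subunits 20 rose and 0 fell, or 21 and 0 adjusted over the list alone. Their median was 0.56 (camera adjusted p = 1.40e-06; adjusted p = 0.343 with an estimated correlation). Among them were PSMB2 (1.95 ± 0.29) and PSMA4 (1.45 ± 0.13). Of 35 deubiquitinases of the USP family, which remove ubiquitin from proteins, 7 rose and 6 fell, the same as adjusted over the list alone (camera adjusted p = 0.420). USP22 rose from 102 ± 8.47 to 316 ± 62.2 CPM (1.68 ± 0.19, adjusted p = 0.00122) and USP49 from 11.5 ± 2.18 to 62.3 ± 26.9 CPM. USP53 fell from 60.8 ± 37.9 to 8.96 ± 3.08 CPM (-2.54 ± 0.47). USP7, named in the study's design through an inhibitor of it, stood at 395 ± 197 CPM against 220 ± 12.7 CPM and did not pass (0.80 ± 0.34, adjusted p = 0.110).

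Growth and NOTCH1 genes were higher. All 28 cell cycle genes rose, also adjusted over the list alone. Their median log2 fold change was 4.96 (camera adjusted p = 5.98e-20; adjusted p = 0.343 with an estimated correlation). UBE2C was 122 times and TOP2A 65.1 times higher. Of 21 ribosome biogenesis genes 15 rose and 0 fell, or 16 and 0 adjusted over the list alone. As a list they had a median of 0.89 (camera adjusted p = 1.67e-06; adjusted p = 0.343 with an estimated correlation). NCL, a nucleolar protein, rose from 564 ± 63.8 to 1611 ± 151 CPM. Of 10 genes of the NOTCH1 pathway 6 rose and 0 fell, or 8 and 0 adjusted over the list alone. On the log2 scale the list's median was 2.60 (camera adjusted p = 0.00731; adjusted p = 0.520 with an estimated correlation). NOTCH1, the receptor often mutated in T-ALL, stood at 565 ± 360 CPM against 90.0 ± 12.5 CPM (log2 fold change 2.39 ± 0.63, adjusted p = 0.0268). Its target MYC stood at 299 ± 169 CPM against 120 ± 13.6 CPM (1.23 ± 0.39, adjusted p = 0.0494). PTCRA, the pre-T cell receptor chain and a NOTCH1 target, stood at 306 ± 333 CPM against 0 reads, at least 7238-fold higher (adjusted p = 0.0431). NOTCH1, MYC and PTCRA lost their calls without any 1 CD3 library (adjusted p 0.0774 to 0.0910, 0.113 to 0.150 and 0.115 to 0.123). The calls of NOTCH1 and PTCRA also ended without 1 or another of the patients (NOTCH1 0.0659 and 0.0731), and that of MYC without 1 patient (0.0749). Over 22 settings NOTCH1 was called in 15 (adjusted p up to 0.119) and MYC in 11 (up to 0.150).

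Immature genes stood opposite to mature ones. Of 16 immature thymocyte genes 13 rose, also adjusted over the list alone, and 1 fell, CD34, a marker of blood stem and progenitor cells chosen after its values were seen (log2 fold change -2.44 ± 0.49). The list's median was 5.94 (camera adjusted p = 9.67e-06; adjusted p = 0.250 with an estimated correlation). Of 20 mature T cell genes 10 fell and 0 rose, also adjusted over the list alone. The median log2 fold change was -3.25 (camera adjusted p = 1.03e-04; adjusted p = 0.343 with an estimated correlation). MAF, a transcription factor of differentiated T cells, went from 149 ± 35.6 to 1.15 ± 0.813 CPM (130 times lower), and KLF2, which controls exit into blood, from 385 ± 22.6 to 21.6 ± 31.8 CPM. Of 20 cytotoxic T and NK cell markers 17 fell and 0 rose, or 19 and 0 adjusted over the list alone. Their median was -5.88 (camera adjusted p = 3.49e-08; adjusted p = 0.343 with an estimated correlation). GNLY was 334 times and GZMH 1744 times lower. Of 17 genes of the T cell receptor complex and its signalling 4 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0675). CD247, the receptor's zeta chain, fell from 298 ± 21.2 to 120 ± 17.8 CPM. KLF2 lost its call without CD3 replicate 3 (adjusted p = 0.0520).

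Of 12 antigen presentation genes 11 fell and 0 rose, or 12 and 0 adjusted over the list alone. As a list they had a median of -4.01 (camera adjusted p = 3.28e-07; adjusted p = 0.343 with an estimated correlation). HLA-DPB1 was 930 times and CD74 368 times lower. Myeloid and B cell markers went both ways. Of 6 myeloid markers 4 fell and AIF1 rose, also adjusted over the list alone (camera adjusted p = 0.106). LYZ, lysozyme, was 143 times lower, at 0.204 CPM against 29.1 ± 14.6 CPM. Of 6 B cell markers MS4A1 was among 2 that fell, at 0.0116 CPM (1 read) against 9.50 ± 1.33 CPM, and CD79A rose, also adjusted over the list alone (camera adjusted p = 0.420). Of 12 NF-kappaB targets 5 fell and 0 rose, or 6 and 0 adjusted over the list alone. On the log2 scale the list's median was -1.91 (camera adjusted p = 0.0162; adjusted p = 0.520 with an estimated correlation). TRAF1 had a log2 fold change of -4.99 ± 0.67, and IL2RA, the high-affinity interleukin 2 receptor chain, fell from 20.8 ± 1.87 to 0.382 CPM. CD79A lost its call without CD3 replicate 1 (adjusted p = 0.0572) or 2 (0.0585).

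The count of 5466 genes was lower with fewer CD3 samples. It was 3114 without CD3 replicate 1, 3181 without replicate 2, 4306 without replicate 3 and 3120 with replicates 1 and 2 averaged, a setting chosen after the data had been seen. Of the 99 named genes that were called, 73 kept their call without any 1 CD3 library and 88 without any 1 patient.

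**Figure D2:**
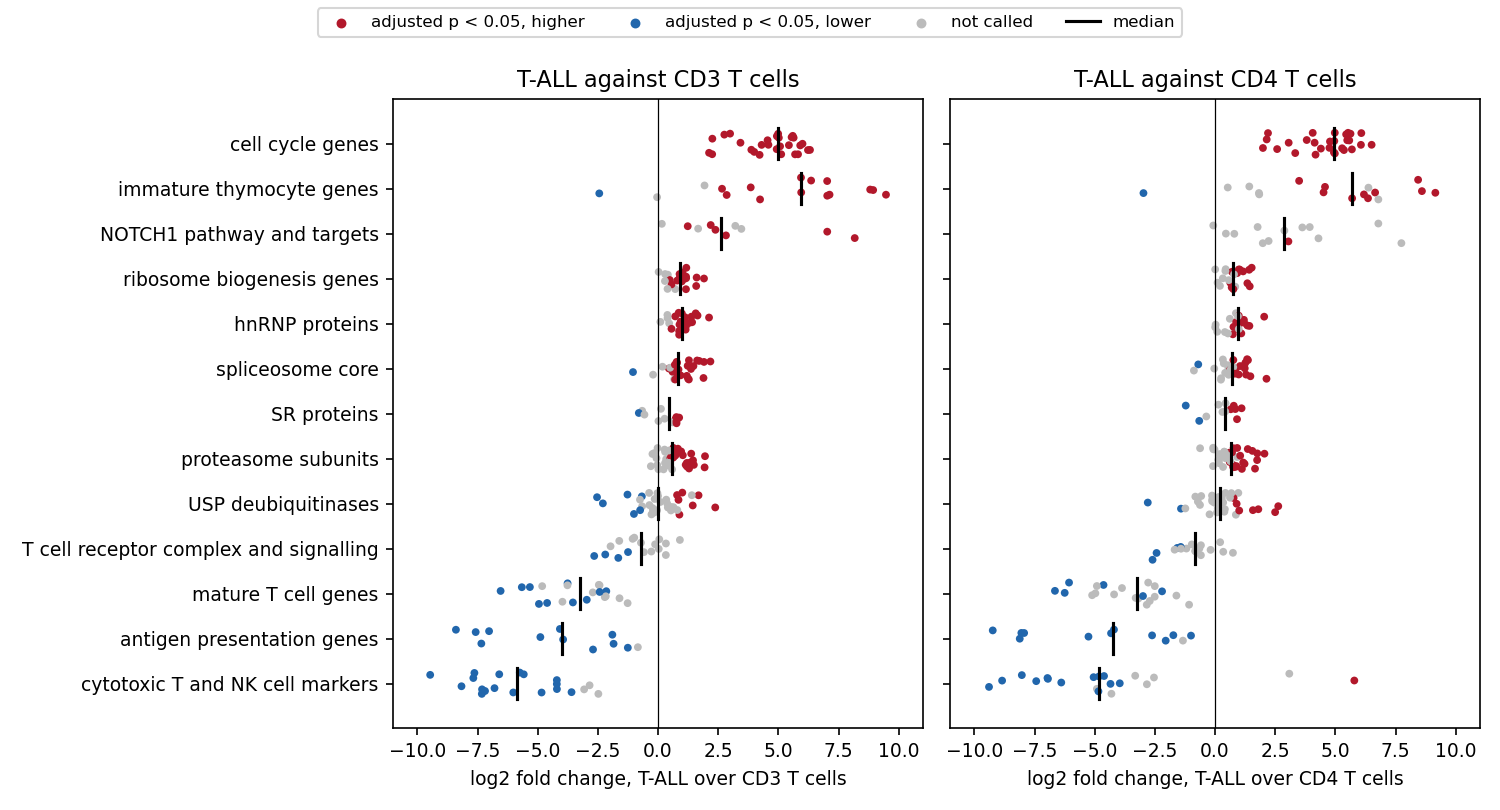
Log2 fold changes of T-ALL over CD3 T cells (left) and over CD4 T cells (right) for the genes of 13 lists, 1 point per gene, with each list's median as a bar and called genes (limma, adjusted p under 0.05) in colour. Cell cycle genes lay at medians of 4.96 and 4.95, and antigen presentation genes at -4.01 and -4.26.

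T-ALL set against CD4 T cells gave the same broad picture. MKI67, a marker of dividing cells, stood at 1091 ± 150 CPM in T-ALL (SD, n = 3 patients) and 20.1 ± 4.76 CPM in CD4 T cells (SD, n = 2), 54.4 times higher. GNLY stood 1003 times lower in T-ALL, at 0.778 ± 0.520 CPM against 781 ± 6.24 CPM, and CD74 593 times lower. SRSF6 did not pass here either, at 302 ± 3.39 CPM in CD4 T cells (log2 fold change 0.14 ± 0.14, adjusted p = 0.476). Of 15047 genes tested with limma, 4592 were called, 2194 higher and 2398 lower in T-ALL.

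The largest rises were again led by CD1B (log2 fold change 9.15 ± 0.97), ARPP21 (8.60 ± 0.72), CD1E (8.44 ± 1.95), FAT1 (7.66 ± 1.08) and MYO7B (7.59 ± 1.96). With them stood IGFBP2, which binds insulin-like growth factors (94.8 ± 20.9 CPM against 0.0566 CPM, 3 reads), and HHIP, an antagonist of hedgehog ligands (88.4 ± 61.2 CPM against 0.0566 CPM, 3 reads). NDST3, a heparan sulphate enzyme (142 ± 156 CPM against 0.0390 CPM, 2 reads), TSPAN7 (6.87 ± 1.42) and CD1A (6.65 ± 0.91) were also among the 10. The largest falls after GNLY and CD74 (-9.24 ± 0.84) included CCL5 (-8.85 ± 0.38) and TRABD2A (-7.80). IL10RA, the interleukin 10 receptor, fell from 604 ± 1.55 to 6.79 ± 5.42 CPM. TC2N, GIMAP4, SGSH and MAF fell too, with log2 fold changes between -6.65 and -6.78. Adjusted p (limma) of the genes named lay between 0.00106 and 0.0435.

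Fewer spliceosome core, hnRNP and USP genes were called than against CD3 T cells, and as many proteasome genes rose. Of 28 spliceosome core genes 14 rose and 1, SF3B1, fell, or 17 and 2 adjusted over the list alone. The median log2 fold change was 0.72 (camera adjusted p = 1.24e-05; adjusted p = 0.606 with an estimated correlation). SF3B1 stood at 539 ± 53.4 CPM against 839 ± 17.6 CPM (-0.70 ± 0.19, adjusted p = 0.0475) and SNRPD1 at 136 ± 19.9 CPM against 29.5 ± 2.89 CPM (2.14 ± 0.16, adjusted p = 0.00176). Of 24 hnRNP genes 14 rose and 0 fell, or 18 and 0 adjusted over the list alone. Their median was 0.95 (camera adjusted p = 3.03e-06; adjusted p = 0.606 with an estimated correlation). HNRNPAB had a log2 fold change of 2.04 ± 0.24. Of 12 SR proteins SRSF1, SRSF2, SRSF3, SRSF10 and TRA2B rose and SRSF5 and TRA2A fell, the same counts as adjusted over the list alone (camera adjusted p = 0.157). SRSF5 moved the most (-1.22 ± 0.15, adjusted p = 0.00638) and alone of these 7 was called in the authors' own fit (0.0141). Of the 8 SR kinases SRPK1 rose (1.34 ± 0.17) and 4 fell, among them CLK4 (-1.20) and CLK1 (-1.07; the same counts adjusted over the list alone; camera adjusted p = 0.443). Of 38 proteasome subunits 20 rose and 0 fell, or 24 and 1 adjusted over the list alone. As a list they had a median of 0.67 (camera adjusted p = 1.47e-06; adjusted p = 0.458 with an estimated correlation). Of 35 USP genes 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.202). USP1, which acts in DNA repair, stood at 207 CPM against 56.1 CPM (1.80, adjusted p = 0.00647). USP7 did not pass, at 395 ± 197 CPM against 229 ± 6.22 CPM (0.62 ± 0.41, adjusted p = 0.299). SF3B1 lost its call without CD4 replicate 1 or 2 (adjusted p 0.261 to 0.269) or without 1 of the patients (0.0607). It was called in 11 of 20 settings (adjusted p 1.13e-04 to 0.269), and not in the authors' own fit (0.243).

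All 28 cell cycle genes rose here too, also adjusted over the list alone. On the log2 scale the list's median was 4.95 (camera adjusted p = 1.16e-19; adjusted p = 0.458 with an estimated correlation). Of 21 ribosome biogenesis genes 12 rose and 0 fell, or 13 and 0 adjusted over the list alone. The median log2 fold change was 0.76 (camera adjusted p = 1.58e-05; adjusted p = 0.458 with an estimated correlation). Of 17 immature thymocyte genes 10 rose and CD34, chosen after its values were seen, fell, also adjusted over the list alone. Their median was 5.70 (camera adjusted p = 1.68e-04; adjusted p = 0.458 with an estimated correlation). The NOTCH1 list of 13 genes had 1 call, LZTFL1 (162 ± 107 CPM against 14.3 CPM; adjusted p = 0.0462), and 0 adjusted over the list alone, beside a camera adjusted p of 0.0215 (adjusted p = 0.619 with an estimated correlation). NOTCH1 (565 ± 360 CPM against 126 ± 8.12 CPM; 1.77 ± 0.78, adjusted p = 0.149) and MYC (299 ± 169 CPM against 190 ± 2.98 CPM; 0.45 ± 0.50, adjusted p = 0.516) did not pass. NOTCH1 was called in 4 of 20 settings (adjusted p down to 0.00261), the authors' own fit among them (0.0392), and MYC in 0. LZTFL1 was not called without 1 or another of the patients (adjusted p 0.0921 and 0.0929), and the NOTCH1 list not without 1 of them (0.0937).

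Of 20 mature T cell genes 6 fell and 0 rose, also adjusted over the list alone. As a list they had a median of -3.24 (camera adjusted p = 2.79e-04; adjusted p = 0.458 with an estimated correlation). Among them were MAF (-6.65 ± 0.45) and CCR7, the lymph node homing receptor (15.6 ± 10.9 CPM against 292 ± 17.2 CPM). Of 12 antigen presentation genes 11 fell and 0 rose, or 12 and 0 adjusted over the list alone. On the log2 scale the list's median was -4.26 (camera adjusted p = 2.38e-07; adjusted p = 0.458 with an estimated correlation). HLA-DPB1 had a log2 fold change of -8.11 ± 0.36. Of 20 cytotoxic markers 13 fell, or 14 adjusted over the list alone. Their median was -4.83, or -4.88 with a gene at 0 reads set to its bound (camera adjusted p = 2.38e-07; adjusted p = 0.458 with an estimated correlation). CD8A, the co-receptor that helper T cells lack, rose (183.8 ± 257 CPM against 0.982 CPM; chosen after its values were seen). Of 17 T cell receptor genes 4 fell and 0 rose, or 3 adjusted over the list alone. The median log2 fold change was -0.82 (camera adjusted p = 0.0335; adjusted p = 0.654 with an estimated correlation). Of 12 NF-kappaB targets 4 fell and 0 rose, or 5 and 0 adjusted over the list alone. Their median was -1.99 (camera adjusted p = 0.0215; adjusted p = 0.619 with an estimated correlation). Of 9 myeloid markers 4 fell and AIF1 rose, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0568). LYZ was 289 times lower, at 0.204 CPM against 58.9 ± 10.4 CPM. Of 5 B cell markers MS4A1 fell and CD79A rose, also adjusted over the list alone (camera adjusted p = 0.817). The call of the T cell receptor list ended without 1 or another of the patients (adjusted p 0.0547 and 0.0755), and that of NF-kappaB targets without 1 (0.0621).

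The count of 4592 genes depended on having both CD4 libraries. It was 783 without CD4 replicate 1 and 773 without replicate 2, where the lone library was assumed to vary like the other groups. Of 100 named genes that were called, 25 kept their call in every setting tried, among them ARPP21, IGFBP2, GNLY, CCL5, TRABD2A, MAF, SNRPD1, PSMA4, MYB, BUB1B, CDC20, TOP2A, MKI67, IL2RA, HLA-DPB1, HLA-DRA and LYZ.

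The comparisons with CD3 and CD4 T cells shared most of their calls. Of 14163 genes tested in both, 3636 were called in the same direction, 1826 higher and 1810 lower in T-ALL, where independent lists of these sizes would share 810. A single gene was called in opposite directions, FMN1, an actin-nucleating formin chosen after its values were seen. Its 6.89 ± 5.09 CPM in T-ALL stood below CD3 T cells (34.7 ± 11.1 CPM; -2.43 ± 0.61, adjusted p = 0.0228) and above CD4 T cells (0.349 ± 0.280 CPM; 2.84 ± 0.75, adjusted p = 0.0466). Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.959 with a covariance of 2.58. The T-ALL libraries are common to both, and 100 simulations of unchanged groups gave r = 0.904, a covariance of 0.277 and 0 genes called in both. The covariance exceeded that of unchanged groups by 2.30. The 3 patients cannot be split into parts of at least 2, so part of the excess of common calls may come from the T-ALL libraries being the same.

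**Figure D3:**
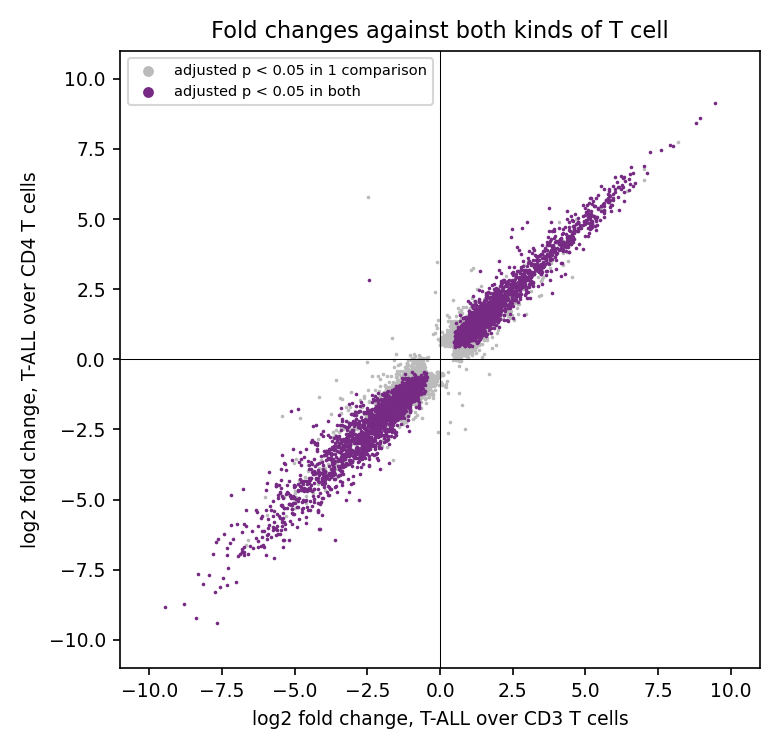
Log2 fold changes of T-ALL over CD3 T cells (horizontal) and over CD4 T cells (vertical), 1 point per gene called in at least 1 comparison (limma, adjusted p under 0.05). The 3636 genes called in both with the same sign lie in the upper right and lower left, and FMN1 is the single gene called in both with opposite signs.

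Against thymus, whose cells are themselves dividing and immature, T-ALL stood out for higher NOTCH1 pathway and ribosome biogenesis genes in the authors' own calls. Over all lists, the authors called 93 members. A refit by edgeR with the averaged T-ALL column called 67. Refits without that column called 38 by edgeR and 52 by limma, and edgeR called 0 without thymus replicate 1 or 2. DTX1, a regulator and target of NOTCH signalling, stood at 513 ± 422 CPM in T-ALL (SD, n = 3) and 1.94 ± 0.570 CPM in thymus (SD, n = 3), 264 times higher. HES1, a direct NOTCH target, stood at 32.0 ± 8.84 CPM against 0.321 ± 0.0769 CPM, 99.5 times higher. HLA-DRA was at 0 reads in T-ALL and 34.9 ± 27.7 CPM in thymus, at least 1473-fold lower. The authors' deposited table held 1545 protein-coding genes, 716 higher and 829 lower in T-ALL, all past their adjusted p of 0.01 and a 2-fold change. SRSF6, SF3B1 and USP7 were not among them. The authors' p-values may count the averaged T-ALL column as a library and would then be too small. Of the 1545 genes, edgeR refits called 1226 with that column and 564 without it.

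In the authors' deposited table the largest rises were led by ADAM33 (56.5 ± 48.5 CPM against 0.0465 CPM, 3 reads), IRX3 (20.1 CPM against 0.0149 CPM, 1 read) and AJAP1 (log2 fold change 9.92, adjusted p = 5.78e-08). The sodium channel gene SCN2A followed (authors' log2 fold change 9.25, adjusted p = 4.99e-10). DTX1 (8.19, adjusted p = 1.09e-30) and PRKCA, protein kinase C alpha (422 ± 82.8 CPM against 2.20 ± 1.85 CPM, 192 times higher), were also there. The SDs of ACTG2, BMP4, RAB27B and the oncogene LMO2 among T-ALL columns exceeded their means (LMO2 80.6 ± 129 CPM). The largest falls included HLA-DRA, HLA-DPA1 (at least 892-fold lower), CD74 (0.0516 CPM against 76.3 ± 54.3 CPM, 1479 times lower) and COL5A3, a collagen chain (at least 1349-fold lower). APP, the amyloid precursor, fell as well (0.0881 ± 0.0529 CPM against 101 ± 31.4 CPM; -9.94, adjusted p = 1.91e-50). IMPACT (at least 718-fold lower), CCDC50, C10orf129 and SLC4A3 were also there.

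Among the authors' deposited calls, 9 of 16 NOTCH1 pathway genes were higher and 0 lower (Fisher's exact test against the table's other genes, adjusted p = 0.00384). For this and the other lists set against thymus, that test counts genes as independent of each other. Its p-values do not measure variation between samples and are a description only. NOTCH1 stood at 563 ± 159 CPM against 137 ± 36.6 CPM (their log2 fold change 2.15, adjusted p = 1.05e-07) and MYC at 197 ± 88.0 CPM against 62.5 ± 19.1 CPM (1.78, adjusted p = 3.47e-04). In 9 refits of the table NOTCH1 was called in 5 (adjusted p up to 0.151) and MYC in 1 (up to 0.353), neither of them without thymus replicate 1, 2 or 3. Of 21 ribosome biogenesis genes 12 were higher and 0 lower (Fisher's exact adjusted p = 7.47e-04), such as UTP20 at 56.8 ± 2.95 CPM against 18.5 ± 4.04 CPM. Immature thymocyte genes went both ways, 2 higher and 6 lower (Fisher's exact adjusted p = 0.341): ERG, an ETS factor, was higher (73.7 ± 63.9 CPM against 0.598 CPM), and CD1C (10.5 ± 1.79 CPM against 524 ± 220 CPM) was lower. Of 28 cell cycle genes 1, MCM4, was in the authors' deposited table (their log2 fold change 1.20).

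Few splicing genes were in the authors' deposited table. None of the SR protein or USP genes was there (0 of 14 and 0 of 35). At the same threshold in the authors' columns, 0 SR proteins passed against CD3 or CD4 T cells either. Of the USP genes 3 were higher and 2 lower against CD3 T cells, and 3 higher and 1 lower against CD4 T cells. Of the 28 spliceosome core and 24 hnRNP genes 1 each was higher, SF3A3 (160 CPM against 81.4 CPM) and SYNCRIP (519 CPM against 251 CPM). The SR kinases CLK1 (163 ± 48.8 CPM against 542 ± 112 CPM; authors' log2 fold change -1.63, adjusted p = 9.36e-05) and CLK4 (-1.60, adjusted p = 1.21e-04) were lower, as they were by limma against CD3 and CD4 T cells. At the thymus threshold in the authors' columns, 2 SR kinases were lower against CD3 T cells and 0 against CD4 T cells. Of 38 proteasome subunits 4 were higher and 0 lower against thymus, PSMD14 at 123 ± 4.60 CPM against 57.4 CPM.

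T cell receptor genes of the authors' deposited table were all lower, 5 of 17 (Fisher's exact adjusted p = 0.121), CD247 at 105 ± 7.51 CPM against 455 ± 86 CPM. Antigen presentation genes were 1 higher and 5 lower of 12 (0.30). Cytotoxic markers were 2 higher and 4 lower of 20 (0.692), with CD8B at 41.6 ± 56.4 CPM against 1234 ± 154 CPM. Mature T cell genes were 3 higher and 1 lower of 20, with ANXA1, annexin A1, at 365 ± 459 CPM against 7.72 CPM. Of 16 myeloid markers 6 were lower and 0 higher (0.0892), S100A8 being at least 215-fold lower. Of 10 erythroid markers HBB, a haemoglobin chain, was at least 441-fold lower (0 reads against 10.5 CPM) and SLC4A1 higher (1.99 ± 0.646 CPM against 0.119 CPM). Of the 12 B cell markers MS4A1 was lower (2 reads against 4.39 CPM) and BLK higher. Of genes called against thymus and CD3 T cells, 297 were higher in both, and 334 lower in both. Another 28 were higher and 47 lower against thymus with the opposite sign against CD3. T-ALL samples enter both comparisons, and how many signs would match in unchanged groups was not simulated.

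Refitted with edgeR's quasi-likelihood test on the recovered reads without the averaged T-ALL column, 564 of the 1545 genes were called. Genes missing from the table were counted as tested and unchanged. With 1 library fewer the calls were 0 (without thymus replicate 1 or 2), 9 (without thymus replicate 3), or 332, 136 and 795 (without each T-ALL column). The 0 calls stood beside 1373 and 1420 genes at an unadjusted p under 0.05 and 276 and 269 calls by limma, and 16 of the 82 named genes kept their call without any 1 T-ALL column.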

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

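The tests of the GNLY level and of the splicing and proteasome lists below were chosen after the result was seen, and those of strand, gene length and other splits before.

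GNLY, the pore-forming granulysin of cytotoxic cells, stood at 785 and 776 CPM in the CD4 libraries and at 303, 291 and 186 CPM in the CD3 libraries. The tables argue against CD8 T cells carried over as the source: at the make-up of the most generous CD3 library, CD8A or CD8B allowed at most 0.392% of the GNLY level. NK cells stay open, since the 7 NK markers allowed 20.4% to 63.0% of it (KLRF1 the most, 5 markers under 50%). Cytotoxic cells among the CD4 T cells are a candidate source: the lowest of NKG7, PRF1, GZMB and GZMH in a CD4 library was GZMB at 57.9 CPM, with CD8A at a mean of 0.982 CPM. Unlike GNLY, all of these effector genes had lower means in CD4 than in CD3 T cells, from NKG7 (222 against 434 CPM) to GZMB (62.4 against 73.0 CPM). On the measure used for NK cells they allowed 43.6% (NKG7), 50.5% (PRF1), 74.7% (GZMH) and 118% (GZMB) of the GNLY level. This source stays open as well. In 1 limma fit with CD3 and T-ALL the rise of GNLY over CD3 T cells did not pass over all genes (log2 fold change 1.72 ± 0.38, adjusted p = 0.364) and passed adjusted over the cytotoxic list alone.

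T-ALL means of the thymus table and the CD3 table correlated at r = 0.927 across 1391 genes, but 85 genes lay over 4-fold apart, 23 of them higher in the thymus table. The shift between tables hardly followed gene length (Spearman rho -0.0332 across genes), which argues against a steady length trend over the 1391 genes. A rank correlation over all of them cannot exclude length for the 85 genes far apart. Counting of reads from the opposite strand may account for part: genes overlapped there by an expressed gene were shifted by 0.195 more on the log2 scale (permutation p = 0.001), and 12 of the 23 genes over 4-fold higher were overlapped, against 13.7% of all (Fisher's exact p = 1.04e-05). Of genes named against thymus, HLA-DPA1, HLA-DPB1, PSME3, TASP1, WT1, LEF1, CCR9, GNL3, HSPD1 and BLK are overlapped in this way. The T-ALL samples behind the columns may also differ between tables, and no biological explanation was tested.

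Splicing and proteasome genes rose against CD3 T cells and hardly appeared against thymus: at the thymus table's threshold in the authors' columns, 24 of 90 members of the spliceosome core, hnRNP and proteasome lists were higher against CD3 T cells and 6 against thymus (Fisher's exact p = 5.03e-04). Like the test after it, this test counts the same genes in both comparisons as separate and independent ones. Its p-value is therefore a description only. A lower number of calls in the thymus table as a whole stays open: at that threshold 1467 protein-coding genes were higher against CD3 T cells and 716 against thymus, and the lists did not shrink detectably more than the other genes (Fisher's exact p = 0.170), though ribosome biogenesis genes went the other way (7 and 12 of 21). Growth state of the normal cells stays open too: of the 28 cell cycle genes higher against CD3 T cells, the share higher against thymus was 3.57%, which it needs. CD4 T cells gave 6 of 90 list members as well, which it does not predict. That count cannot decide, as fewer protein-coding genes passed against CD4 than against CD3 T cells (1845 and 2767). By limma the medians of the spliceosome core, hnRNP and proteasome lists were 0.72, 0.95 and 0.67 against CD4 T cells. Against CD3 T cells they were 0.82, 0.98 and 0.56. Thymus also differs from the T cells in tissue make-up and read format, which were not tested.

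In 1 of the 5 T-ALL libraries the mean log2 CPM of SR proteins lay apart, at 8.44 against 8.08 to 8.14 (gap of 0.837 of the group's range). For hnRNP proteins 1 library stood at 9.54 against 9.01 to 9.15 (0.736). For USP deubiquitinases 1 library stood at 5.59 against 6.08 to 6.28 (0.710). For SF3B1 1 library stood at 8.53 against 9.11 to 9.28 (0.781). These were 4 of 32 measures tested, of which chance marks about 1 in 20, and pairs of these libraries share a patient.

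Set against CD3 T cells, CD4 T cells had higher levels of the spliceosome core (median log2 difference 0.21; camera adjusted p = 0.00558; adjusted p = 0.852 with an estimated correlation). Mitochondrially encoded genes were also higher as a list in CD4 T cells (median 0.51; camera adjusted p = 0.00247; adjusted p = 0.852 with an estimated correlation), though 0 members of either list were called by limma. Their share of reads was 4.52%, 4.24% and 6.99% in CD3 replicates 1, 2 and 3, and 7.16% and 6.48% in the CD4 libraries. CD3 replicate 3 thus lay between the CD4 libraries, and only CD3 replicates 1 and 2 lay below them.

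For the count of 5466 genes against CD3 T cells, 1 of the 10 splits of the 6 units into 3 and 3, the real one, gave as many. The highest other split gave 0 genes by limma. With 10 splits a share under 0.05 cannot be reached.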

How the results depend on the processing

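The use of limma in place of edgeR's quasi-likelihood test, that test's fits on recovered reads, the pseudocounts, the averaged CD3 replicates, the first library of each patient and the thymus refits were tests chosen after the data were seen, and the other alternatives before. No called gene that was named and no called list changed its direction in any setting, while SRSF6, not called, lay on either side of 0 against CD3 T cells (log2 fold change -0.08 to 0.15). Against CD3 T cells 69 of 99 named calls held in all 22 settings, against CD4 T cells 25 of 100 in all 20, and against thymus 0 of 82 in all 9. Scaling, filter, pseudocount, unit of replication and edgeR tests left the CD3 count between 4699 and 5850 and the CD4 count between 3632 and 4804, and the authors' own p-values gave 4857 and 3451. With CD3, CD4 and T-ALL in one fit the counts were 6653 and 5967. DESeq2 gave 6219 against CD3 and 6894 against CD4 T cells, the cause of which was not tested. Stricter thresholds lowered the counts by construction: at an adjusted p under 0.01 to 2770 (CD3), 1711 (CD4) and 1406 (called in both), and by Bonferroni to 197 (CD3), 21 (CD4) and 577 (thymus). With CD3 replicates 1 and 2 averaged, 3120 genes were called. Leaving out 1 library or patient gave 3114 (without CD3 replicate 1) to 6447 genes against CD3, 773 (without CD4 replicate 2) to 6036 against CD4, and 0 (without thymus replicate 1 or 2) to 795 against thymus by edgeR, with 269 to 420 by limma without 1 thymus library. Fewer samples are part of that construction, and no other cause was tested. For thymus, edgeR called 564 and limma 946 genes without the averaged column, and edgeR 1226 with it. List members called there went from the authors' 93 to 67 in the edgeR refit with the averaged column. Without that column they were 38 by edgeR and 52 by limma, and between 0 and 49 with 1 library fewer. The step from 93 to 67 thus came with the refit and not with leaving out the column. With an estimated correlation, camera called 0 of 24 lists in place of 11 against CD3 T cells and 0 in place of 12 against CD4 T cells. At an unadjusted p under 0.05 it had 2 and 1, and fry called 16 and 15. All other settings gave 11 to 13 lists.

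With the replicate number as a block over single libraries (replicate block), 3595 genes were called against CD3 and 4162 against CD4 T cells. The numbers did not pair the samples, since T-ALL libraries are numbered within each patient: differences between numbers 1 and 2 correlated at -0.39 and -0.25 with those of CD3 T cells and at 0.07 and 0.25 with those of CD4 T cells, across genes. No paired analysis was possible, because the labels name no patient for any CD3, CD4 or thymus library. The thymus table's T-ALL columns are moreover tied to the group only. Other scalings, no filter, DESeq2, the exact test, patients as units and the camera variants were not run for thymus, whose table holds only called genes, nor was a fit of all 4 groups. Depth limits levels under 0.149 CPM per library, and simulated 2-fold changes, given the same spread for all genes, were called in 10% of cases.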

Other observations

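The tests of CD4 against CD3 T cells and the length trend were chosen after the result was seen, and the lists had been fixed before.

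CD8 lineage genes were at far lower levels in CD4 than in CD3 T cells, though neither CD8A nor CD8B passed limma over all genes in a fit with T-ALL. Of 20 cytotoxic markers 0 passed over all genes, and adjusted over the list alone CD8A and CD8B fell and GNLY rose (camera adjusted p = 0.0597; adjusted p = 0.852 with an estimated correlation). CD8A stood at 677, 681 and 248 CPM in the CD3 libraries and at 1.21 and 0.755 CPM in the CD4 libraries (log2 fold change -8.29 ± 1.16, limma adjusted p = 0.216), and CD8B went the same way (-6.18 ± 1.25). FOXP3, the factor of regulatory T cells, lay on the other side (1.52 ± 0.26, adjusted p = 0.313). These 3 genes were chosen after their values were seen. With limma on CD3, CD4 and T-ALL in one fit, 0 of 15024 genes passed and 1395 had an unadjusted p under 0.05. Fitted on the 5 normal libraries alone, edgeR called 41 of 14145 genes, 16 higher and 25 lower in CD4 T cells, and limma 48.

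Stress and signalling genes of T-ALL went both ways. Of 10 heat shock genes 5 rose and DNAJB1 fell against CD3 T cells, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0675), HSP90AA1, a chaperone, from 675 ± 199 to 1381 ± 38.3 CPM. Against CD4 T cells 2 rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.243), and 3 were higher in the authors' deposited thymus table. Of 17 immediate early genes 3 rose and 5 fell against CD3 T cells, also adjusted over the list alone (camera adjusted p = 0.825), JUNB from 353 ± 98.1 to 33.6 ± 25 CPM. Against CD4 T cells 2 rose and 2 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.895). Of 20 in the list, 1 was higher and 7 lower than in thymus in the authors' deposited table, among the 7 EGR3, induced by receptor signals, at 0.116 CPM against 9.34 CPM. Of 19 interferon response genes 2 rose and 5 fell against CD3 T cells and 0 rose and 5 fell against CD4 T cells, also adjusted over the list alone (camera adjusted p = 0.317 and 0.243), IRF7 from 49.9 to 9.46 CPM in the former, while 2 were higher than in thymus. Of 9 histone genes 1 rose and 3 fell against CD3 T cells and of 8 against CD4 T cells 1 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.171 and 0.294), and 2 were lower than in thymus. HSP90AA1 lost its call against CD3 T cells without CD3 replicate 1 (adjusted p = 0.0539).

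Of 8 transcription factors that act as T-ALL oncogenes, MYB rose (457 ± 87.9 CPM against 13.3 ± 0.220 CPM in CD3 and 16.7 CPM in CD4 T cells) and MEF2C fell in both comparisons, also adjusted over the list alone (camera adjusted p = 0.258 and 0.472). Against thymus 3 were higher in what the authors deposited, among them LYL1. Without CD4 replicate 1 MEF2C lost its call against CD4 T cells (adjusted p = 0.0602). Of 20 genes recurrently altered in T-ALL 8 rose and 3 fell against CD3 T cells, or 8 and 4 adjusted over the list alone, and 5 rose and 2 fell against CD4 T cells, also adjusted over the list alone (camera adjusted p = 0.258 and 0.395). EZH2, a histone methyltransferase, rose from 25.4 ± 1.13 to 167 ± 42.2 CPM, WT1 was at 11.4 ± 7.95 CPM against 0 reads (at least 270-fold higher), and JAK1, a cytokine receptor kinase, fell from 617 ± 92.5 to 147 ± 53.2 CPM against CD3 T cells. Against thymus 1 was higher and 3 lower in the authors' deposited table, among them LEF1 (548 CPM against 1674 CPM).

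Of 13 mitochondrially encoded genes 0 passed limma against CD3 T cells, also adjusted over the list alone (1 at an unadjusted p under 0.05, 1 by the authors' edgeR fit, camera adjusted p = 0.467). MT-CO1 stood at 12799 ± 5032 CPM against 10961 ± 2007 CPM in CD3 T cells, and MT-ND3 alone fell against CD4 T cells (708 ± 105 CPM against 1199 ± 60.8 CPM), or 0 adjusted over the list alone (camera adjusted p = 0.417). MT-ND3 lost its call without CD4 replicate 1 (adjusted p = 0.274) or 2 (0.246) or without 1 of the 3 patients (0.0529). Of platelet markers 1 was tested against CD3 T cells and did not pass, and 1 of 2 fell against CD4 T cells, ITGA2B (0.147 CPM against 1.86 CPM; adjusted p = 0.0544 without CD4 replicate 2). For thymic stroma these were 1 tested without a call and 1 of 2 fallen, PRSS16 (1 read against 1.29 CPM). No erythroid marker was high enough to test against T cells (0 tested), and against thymus HBB was lower and SLC4A1 higher in the authors' deposited table. No mitochondrially encoded, platelet or stroma gene was in that table (0 of each).

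Between libraries of a patient, log2 differences followed gene length more (absolute Spearman rho 0.130 and 0.358 across genes over 5 CPM) than between CD3 libraries (0.00170 to 0.0343).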
